A study of Apis mellifera with 15 samples.

How the data were processed

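Brain messenger RNA of forager honey bees (Apis mellifera) was sequenced in 15 libraries, 5 for each of 3 groups: a solvent control, thiacloprid at 25 ng per bee and thiacloprid at 250 ng per bee. Per the labels, bees from an unpolluted site were kept in bottles in the laboratory and took the compound with sucrose solution for 72 h, and each replicate was a separate pool of 5 dissected brains, so that the spread between replicates holds differences between pools of animals as well as technical differences. The libraries were made with a poly-A stranded kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. Per the labels, the description of 14 libraries starts with the date-like string 20190809 and that of replicate 1 at 250 ng/bee with 20191023, and what the string stands for is not given in the sources used here.

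The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.1.0, SAMtools 1.7, StringTie 2.0.2 and DESeq2 1.22.2, without the role or settings of each, and the genome build and the use of strand in counting are not given in the sources used here. The deposited gene table holds estimated counts for 12112 genes in the 15 libraries. Each of these deposited counts equals the summed coverage times length of the gene's transcripts divided by a read length of 75, within 1 count, for 100% of the genes in every library, which marks the counts as estimated counts rather than direct tallies of reads, and they were used rounded to whole numbers as deposited. The authors also deposited 1 transcript table per library, which per the file headers gives the FPKM and the coverage of 28276 transcripts. Coverage was used for the check of the counts, and FPKM for the transcript test, for transcript lengths and for the length slope between transcripts of 1 gene. All 12112 gene names were found in the reference gene table of assembly Amel_HAv3.1, and 12069 genes (99.6%) had the same start and end in the deposited transcript tables and in that assembly, so coordinates are printed as the deposited tables give them. The files carry no product names. Of the 12112 genes, 388 have a symbol other than a locus, microRNA or transfer RNA identifier, and gene lists were matched on symbols and on the synonyms of the reference table.

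Total counts per library were 9226059 to 11500655 in the control, 8123655 to 10067138 at 25 ng/bee and 6834898 to 29208991 at 250 ng/bee. No library repeated another: the smallest chi-square per degree of freedom was 19.5 between 2 libraries of a group and 18.9 between libraries of different groups, so all 15 were counted as replicates. A total of 872 genes had no count in any library. After the low-count filter of edgeR (filterByExpr on the groups), 9560 genes holding 99.96% of the counts were tested, with a common biological coefficient of variation of 0.219. On data simulated from these libraries with 200 changed genes, edgeR recovered 44.8%, 77.6% and 97.0% of the genes changed 1.5-, 2- and 3-fold for 25 ng/bee against the control and 38.8%, 74.6% and 90.9% for 250 ng/bee against the control, over 9560 genes each. False calls at 250 ng/bee were 4 in edgeR, 4 in limma-voom and 19 in DESeq2. The simulated genes were independent and no library was set apart, so these shares may overstate recovery in the real libraries. The transcript test recovered 5.97%, 20.9% and 51.5% of the transcripts changed 1.5-, 2- and 3-fold for 25 ng/bee against the control and 7.46%, 26.9% and 51.5% for 250 ng/bee, over 14930 transcripts.

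The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, two-sided) on the estimated counts, with TMM scaling and all 15 libraries in 1 fit with group as the only term, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The family held 3 pairwise comparisons (each dose with the control and the doses with each other) and a test of any difference among the 3 groups. CPM values are scaled by TMM and given as mean ± SD, and log2 fold changes are given with their standard errors. Genes are not independent of each other, so counts at an unadjusted p under 0.05 are descriptive beside the 478 genes that chance gives on average. The tests of genes, lists, transcripts and dose overlap, the samples in each fit, the named-gene rule and 32 gene list names were fixed before the data were examined. Members were matched to the symbols in the files before any test, and matches that did not belong to a list's name were dropped. Of the 32 lists, 5 had no tested gene and 6 had 1 or 2, which left 21 lists with at least 3 tested genes. These were tested with camera (limma 3.58.1, two-sided) at a preset correlation of 0.01 between genes, again with the correlation estimated for each list, and with fry. Lists for tissues that a dissected brain can carry along (hypopharyngeal and salivary glands, fat body, muscle, retina, odorant-binding and chemosensory genes, cuticle) and for glia and neurons were also compared as mean log2(CPM + 1) per library with exact permutation tests. Transcripts with an FPKM of at least 1 in at least 5 libraries (14930) were tested with limma on log2(FPKM + 1), a scale that understates changes of low transcripts.

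Transcript length per gene was the mean length of its transcripts weighted by their mean FPKM. For each library, the slope of log2 CPM (as deviation from the gene's mean) on log2 length was taken over genes with a mean log2 CPM over 3. Slopes were compared between groups with two-sided exact permutation tests, which were not among the planned tests. A length correction removed the loess trend (span 0.5) of each library through offsets. List medians were also set beside 10000 random lists of the same size, matched in length and in mean expression and called length-matched below.

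Genes were named by a fixed rule: for each dose, the 10 largest rises and the 10 largest falls among genes past the threshold with a symbol, or, with fewer than 10 such genes in both directions together, the 5 genes of lowest p in each direction, named as not past the threshold. The rule added up to 4 members of lowest p of each list and a fixed set of detoxification, receptor, storage, gland and immune genes, of which Cyp9q1, Cyp9q2 and Cyp9q3 were not matched by symbol and Def2 was not among the tested genes. For 250 against 25 ng/bee, the rule took 5 genes in each direction. Since no gene passed with all 15 libraries, the genes of lowest p were taken. Genes named outside this rule were chosen after their values were seen and are marked so. A few genes that the rule took are not reported here.

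Alternatives were DESeq2 1.42.0, limma-voom with sample weights, DESeq2's size factors or library totals in place of TMM, scaling without the 20 most abundant genes, no low-count filter or a mean count of at least 10, only the groups compared, the replicate number as a block, 1 surrogate variable (sva 3.50.0), only libraries with the 20190809 prefix, stricter thresholds, each library left out in turn, and for transcripts a pseudocount of 0.1, no filter and quantile normalization. Length correction, gland and muscle scores as covariates and combinations with the prefix were chosen after seeing the data. Near-identical gene copies, overlapping genes and antisense partners were not examined, and counts of such genes are uncertain where the counting could split reads between them.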

Results

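Brain transcript levels were measured in 15 libraries of forager honey bees, 5 from bees fed sucrose solution with solvent and 5 each from bees fed 25 or 250 ng per bee of thiacloprid, a neonicotinoid insecticide that acts on nicotinic acetylcholine receptors. Each library came from a pool of 5 brains. Total counts per library were 9226059 to 11500655 in the control, 8123655 to 10067138 at 25 ng/bee and 6834898 to 11180170 in replicates 2 to 5 at 250 ng/bee. Replicate 1 at 250 ng/bee, the only library whose label starts with 20191023, held 29208991 counts. It also stood apart in a principal component analysis, at -37.5 and -39.4 on the first and second components, which held 17.4% and 12.6% of the variance. The most abundant transcripts with a symbol were those of Mrjp1, a major royal jelly protein, and Hbg3, an alpha-glucosidase of the hypopharyngeal gland, with a mean of 6.59% and 3.65% of all counts.

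The first comparison asked which brain genes differ after the lower dose. At 25 ng/bee, no gene or gene list passed its test. Nrk1 had 36.6 ± 3.47 CPM at 25 ng/bee and 28.4 ± 2.94 CPM in the control (SD, n = 5), a log2 fold change of 0.36 ± 0.10 (SE). All 5 exposed libraries lay above the control mean (adjusted p = 0.998 in edgeR). CPR22, a cuticular protein, differed by -1.51 ± 0.44 on the log2 scale. In edgeR (two-sided), 0 of 9560 genes passed, with 235 at an unadjusted p under 0.05 (101 higher, 134 lower), fewer than the 478 that chance gives on average. DESeq2 and limma-voom with sample weights also passed 0 genes, with 285 and 588 at an unadjusted p under 0.05.

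Genes of immunity went both ways at 25 ng/bee. PGRP-S3 and Pgrp-s2, peptidoglycan recognition proteins, had log2 fold changes of 0.63 ± 0.23 and -0.55 ± 0.18, and Apid1, which encodes the antimicrobial peptide apidaecin, had -2.44 ± 1.03, which turned to 0.25 without control replicate 4. Of the 12 tested members of the immune list, 9 were lower and 3 higher, with a median of -0.15 (camera adjusted p = 0.225, 0.0381 without control replicate 1, and adjusted p = 0.764 with an estimated correlation). None passed in edgeR, whether adjusted over all genes or adjusted over the list alone. Among neuropeptides, Apime-ASTA (allatostatin A) differed by -0.48 ± 0.19, Pburs (a bursicon subunit) by -0.37 and Crz (corazonin) by 0.45, and the list's median of -0.23 did not pass (camera adjusted p = 0.207). CSP3, a chemosensory protein, differed by 0.54 ± 0.24, and the odorant-binding and chemosensory list had a median of -0.05 and a mean of 0.03 over 23 genes (adjusted p = 0.979).

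All 7 listed cytochrome P450 genes were lower at 25 ng/bee, with a median log2 fold change of -0.28 in the direction of all 5 exposed libraries. The family includes enzymes of insecticide detoxification. Like the other lists, this one holds only genes matched by symbol or synonym, and Cyp9q1, Cyp9q2 and Cyp9q3 were not matched. The list did not pass (camera adjusted p = 0.0599, and adjusted p = 0.764 with an estimated correlation), and none of its members passed, whether over all genes or adjusted over the list alone. LOC551028, listed as CYP6AS13 in the reference table, had -0.26 ± 0.16 and Cyp314a1, which makes the active form of ecdysone, had -0.26 ± 0.18. All 15 receptors for amines and amino acid transmitters (median -0.11) and all 8 synaptic vesicle and active zone genes (median -0.14) were also lower, each with a camera adjusted p = 0.0925 (adjusted p = 0.764 with an estimated correlation). Of the 10 nicotinic receptor subunits, 6 were lower and 4 higher, with a median of -0.05 (adjusted p = 0.776), and nAChRb1 had -0.36 ± 0.24, nAChRa2 -0.18 ± 0.13, nAChRa8 -0.10 ± 0.11 and nAChRa1 0.01 ± 0.18. Leaving out control replicate 1, 2 or 5 let 4, 1 and 2 lists pass, and leaving out replicate 1 or 2 at 25 ng/bee let 1 and 3 lists pass. The P450 list passed without control replicate 2 (adjusted p = 0.00225), control replicate 5 (0.0470), replicate 1 (0.00759) or replicate 2 at 25 ng/bee (0.0407). Receptors passed without control replicate 1 (0.0241) or replicate 2 at 25 ng/bee (0.00152), and so did synaptic genes (0.0267 and 0.0189). With the replicate number as a block, the P450 list (0.0134) and the receptors (0.0459) passed in camera with its preset correlation. Most random splits of the control and 25 ng/bee libraries also passed at least 1 list at this correlation.

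Muscle genes, which mark tissue carried along with the brain, had a median of 0.05 at 25 ng/bee (camera adjusted p = 0.207, and adjusted p = 0.857 with an estimated correlation), with 0.53 ± 0.73 for the troponin C gene TpnCIIIa and 0.30 ± 0.36 for TpnCIIIb. The list passed, higher, without control replicate 5 (3.20e-06), and had 0.678 without control replicate 1. Fat body and haemolymph storage proteins had a median of -0.30 and a mean of -0.22 (adjusted p = 0.207, 0.0267 without control replicate 1, and adjusted p = 0.764 with an estimated correlation), with -0.53 for Hex70a, -0.33 ± 0.15 for the iron-binding Tsf1 and 0.09 ± 0.57 for Vg, the egg yolk precursor vitellogenin. Adjusted p was 0.258 for learning and memory genes (4 of 4 lower, For at -0.30), 0.267 for nuclear-encoded oxidative phosphorylation (CytC at 0.11) and 0.312 for cuticle genes. It was 0.776 for glia and for the retina list, whose median was 0.01 and mean -0.17 (Lop2, a long-wavelength opsin, at -0.79 ± 0.40), 0.817 for the cytosolic ribosome and 0.965 for neurons. Gland products (Mrjp1 at -0.17 ± 0.59), antioxidant enzymes, heat shock genes (Hsp90 at 0.32), other detoxification and juvenile hormone, ecdysone and insulin genes (Jhe at -0.28) each had an adjusted p = 0.979. Heat shock genes had a median of -0.01 and a mean of 0.03, other detoxification genes had a median of 0.02 with a test that pointed down, and the hormone list had a median of -0.03 and a mean of 0.00.

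The second comparison asked the same of the higher dose. At 250 ng/bee, the lists of transmitter receptors and synaptic genes were lower in camera with its preset correlation. Those of ribosomal, respiratory chain and muscle genes were higher in the same test. No single gene passed with all 15 libraries. None of these 5 lists passed with a correlation estimated from the data (adjusted p = 0.657 to 0.708 with an estimated correlation). Of the 15 receptors for amines and amino acid transmitters, 13 were lower, with a median log2 fold change of -0.27 that all 5 exposed libraries shared in direction, and Glurb and mGlutR1, metabotropic glutamate receptors, had -0.36 ± 0.11 and -0.33 ± 0.14. All 8 synaptic vesicle and active zone genes were lower (median -0.29, all 5 libraries), among them Nrx-1, a neurexin that holds synapses together, at -0.74 ± 0.24 and Syx1A, a syntaxin of vesicle fusion, at -0.28 ± 0.10. All 7 listed cytosolic ribosome genes were higher (median 0.36, 3 of 5 libraries), with 0.55 ± 0.19 for Rpl41 and 0.43 ± 0.22 for RpL32. Of 8 listed oxidative phosphorylation genes, 6 were higher (median 0.19, all 5 libraries), with 0.37 ± 0.13 for Ndufs5 and 0.46 ± 0.20 for Uqcr11, subunits of complexes I and III. The lists hold only genes matched by symbol or synonym, so members of these families under other identifiers are not covered. Of 7 muscle genes, 6 were higher (median 0.81, 4 of 5 libraries), with the troponin C genes TpnCI at 0.81 ± 0.45, TpnCIIIa at 0.91 ± 0.73 and TpnCIIIb at 0.45 ± 0.35.

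Camera's two-sided test passed these 5 lists of 21 at 250 ng/bee, and none passed with an estimated correlation or in fry. Receptors and oxidative phosphorylation each had an adjusted p = 0.00729 (adjusted p = 0.657 with an estimated correlation), the ribosome list had 0.00729 (adjusted p = 0.708 with an estimated correlation), and muscle and synaptic genes had 0.0139 and 0.0151 (adjusted p = 0.657 with an estimated correlation for each). None of their members passed in edgeR, whether over all genes or adjusted over the list alone. Ribosome and respiratory chain transcripts were short (median 565 and 878 nt), muscle transcripts were 1108 nt, and receptor and synaptic transcripts were long (3864 and 5631 nt), beside 2112 nt for all tested genes. With the length correction, chosen after seeing the data, adjusted p was 0.560 for the ribosome, 0.590 for oxidative phosphorylation, 0.0625 for receptors, 0.110 for synaptic genes and 0.0300 for muscle. Without replicate 1 at 250 ng/bee, adjusted p was 0.769 for the ribosome (median 0.05), 0.121 for oxidative phosphorylation, 0.0961 for muscle and for synaptic genes, and 0.0326 for receptors (adjusted p = 0.722 with an estimated correlation). The synaptic list also missed the threshold without control replicate 5 (0.0614) or replicate 3 at 250 ng/bee (0.0562), and the muscle list without control replicate 1 (0.0584) or 2 (0.101) or replicate 3 (0.0562) or 4 (0.164) at 250 ng/bee. As mean log2(CPM + 1), muscle genes were at 5.16 ± 1.07 in the control (SD, n = 5) and 0.85 higher at 250 ng/bee (SD 0.696, n = 5, two-sided exact permutation p = 0.143, adjusted p = 0.952 over 24 marker comparisons).

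**Figure D1:**
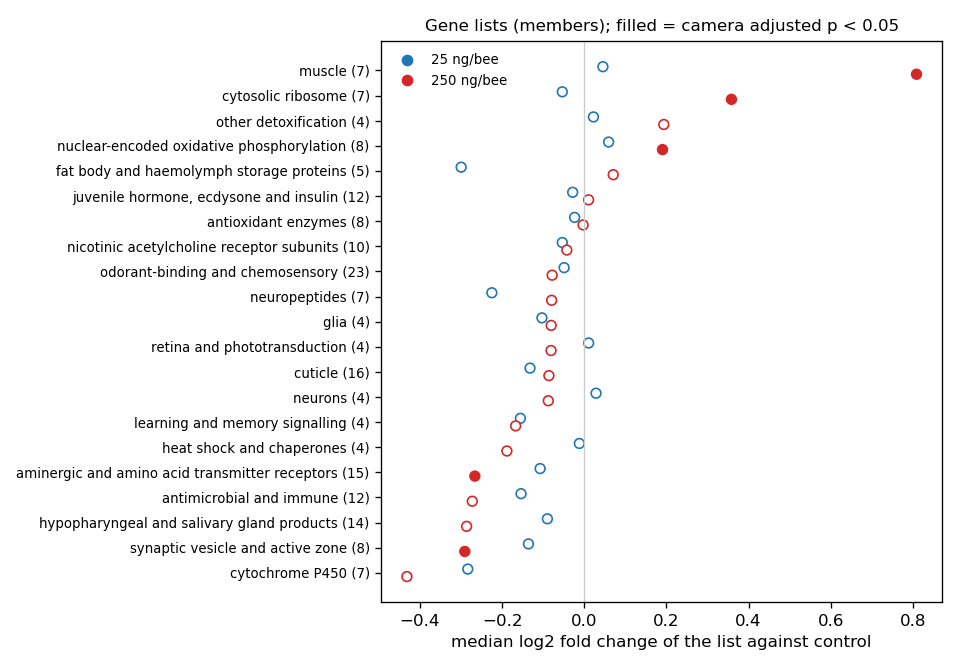
Median log2 fold change of each gene list against the control (horizontal axis) at 25 ng/bee (blue) and 250 ng/bee (red), with the number of tested members after each name; filled circles passed camera at an adjusted p under 0.05. At 250 ng/bee muscle (0.81), ribosome (0.36) and oxidative phosphorylation genes (0.19) lay above 0 and transmitter receptors (-0.27) and synaptic genes (-0.29) below, and no list passed at 25 ng/bee.

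Among single genes at 250 ng/bee, the lowest p-values with a symbol on the higher side belonged to Nrk1 (0.42 ± 0.10, 38.2 ± 4.33 CPM, SD, n = 5), A4 (1.53 ± 0.47, 179 ± 122 CPM against 62.1 ± 20.7 CPM), JHBP-1, named as a juvenile hormone-binding protein (1.03 ± 0.33), Rpl41 and PHRF1 (0.24 ± 0.086). Among those on the lower side were the chromatin remodelling gene NFRKB (-0.39 ± 0.11, 102 ± 11.3 CPM against 134 ± 9.53 CPM), the adhesion scaffold gene Nedd9 (-0.46 ± 0.14), Glurb and Fstl5 (-0.43 ± 0.13). All 5 exposed libraries lay on the same side of the control mean for each of these genes except A4 and Rpl41, with 4 of 5. Their adjusted p in edgeR was 0.277 to 0.339. Nrk1 lies on chromosome 9 (11436038 to 11436628), A4 on chromosome 2 (15188032 to 15188900) and NFRKB on chromosome 11 (15399554 to 15406012) of assembly Amel_HAv3.1.

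Levels of 3 immune genes varied widely between control pools, and their difference at 250 ng/bee shrank without control replicate 4. Apid1, on chromosome 16 (4518604 to 4520315), had 81.3 ± 43.8 CPM at 250 ng/bee, 148 ± 160 CPM at 25 ng/bee and 808 ± 1529 CPM in the control (SD, n = 5), with 3538 CPM in control replicate 4 and 50.3 to 299 CPM in the other 4 control libraries. Its log2 fold change was -3.32 ± 1.07, beside -3.17 ± 1.10 for LOC406142 and -2.10 ± 0.75 for LOC406144, 2 genes without a symbol in the fixed immune list. These 3 of the 12 members passed adjusted over the list alone (adjusted p = 0.0497 in edgeR each), and 0 passed over all genes. For none of the 3 did the exposed libraries all lie below every control library. Without control replicate 4, which held the highest value of each, the log2 fold changes were -0.62, -1.60 and -0.85. Def1, which encodes a defensin, had 0.03 ± 0.39, and the list as a whole (8 lower, 4 higher, median -0.27, mean -0.79) did not pass (camera adjusted p = 0.260, 0.0366 with the length correction at camera's preset correlation, and with all 15 libraries uncorrected adjusted p = 0.837 with an estimated correlation).

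**Figure D2:**
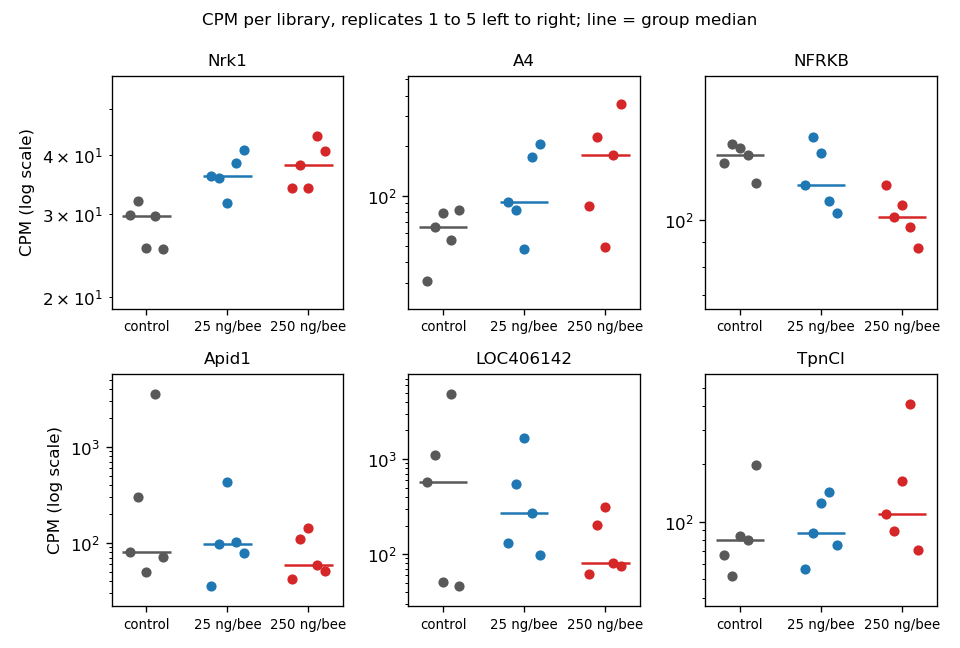
CPM (logarithmic vertical axes) of 6 genes in each library of the control, 25 ng/bee and 250 ng/bee groups, replicates 1 to 5 from left to right, with lines at group medians. Nrk1 lay above the control mean in every exposed library, NFRKB below it in every library at 250 ng/bee, Apid1 reached 3538 CPM only in control replicate 4, and A4 and TpnCI varied widely at 250 ng/bee.

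Detoxification genes and nicotinic receptor subunits did not pass as lists at 250 ng/bee. Of the 7 P450 genes matched by symbol or synonym, 6 were lower (median -0.43, mean -0.25, 4 of 5 libraries), with LOC551028 at -0.43 ± 0.16 and LOC724946, listed as CYP6AS11 in the reference table, at -0.67 ± 0.27 (camera adjusted p = 0.0561, and adjusted p = 0.657 with an estimated correlation). In camera with its preset correlation, the list passed without control replicate 2 (0.0137) and without replicate 1 at 250 ng/bee (0.0326). Without replicate 1 the list had an adjusted p = 0.722 in camera with an estimated correlation. At the preset correlation it also passed with the length correction (0.0300), the replicate block (0.00751), DESeq2's size factors (0.0400) and no low-count filter (0.0315). Other detoxification genes had a median of 0.19, a mean of -0.09 and a test that pointed up (adjusted p = 0.588), with GstS1, a glutathione transferase, at 0.26. Of the 10 nicotinic receptor subunits, which thiacloprid targets, 7 were lower and 3 higher, with a median of -0.04 (0.03 without replicate 1 at 250 ng/bee and 0.08 with the length correction, camera adjusted p = 0.558). The subunit gene nAChRb1 had 5.49 ± 1.25 CPM against 8.50 ± 2.34 CPM (SD, n = 5), a log2 fold change of -0.62 ± 0.24, and nAChRa8 had -0.27 ± 0.11, nAChRa2 -0.27 ± 0.13 and nAChRa1 -0.05 ± 0.18, with an adjusted p in edgeR of 0.356 or more and none passing adjusted over the list alone.

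Lists of other functions did not pass at 250 ng/bee. The odorant-binding and chemosensory list had a median of -0.08 (camera adjusted p = 0.475, 15 of 23 lower, and adjusted p = 0.857 with an estimated correlation), with CSP1 at -0.62 ± 0.25 and Obp15 at -1.94 ± 0.82. It passed without control replicate 2 (0.0293) and with the length correction (0.000442, median -0.23), both in camera with its preset correlation. Its transcripts were short, with a median of 703 nt. Heat shock and learning genes were lower in 4 of 4 members each (adjusted p = 0.573 and 0.613), with -0.24 for Hsc70-3. Gland products (median -0.29, AGLU2 at -0.36 and Hbg2 at 0.95 ± 0.57), fat body proteins (0.07, HEX70b at 0.29), glia (-0.08), neurons (-0.09, Para at -0.20), antioxidant enzymes, neuropeptides and hormone genes each had an adjusted p = 0.856. The test pointed up for antioxidant enzymes with a median of -0.00, for neuropeptides with a median of -0.08 and a mean of 0.23 (Crz at 0.66, Burs at -0.56), for cuticle genes with a median of -0.09 and a mean of -0.13 (adjusted p = 0.946, CPR4 at 0.35) and for the retina with a median of -0.08 and a mean of 0.04 (adjusted p = 0.950). Of the hormone genes, whose median was 0.01, 7 were higher and 5 lower, with E75, an ecdysone-induced receptor, at 0.25.

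In edgeR (two-sided), 0 of 9560 genes passed at 250 ng/bee with all 15 libraries, with 1144 at an unadjusted p under 0.05 (429 higher, 715 lower) and a smallest adjusted p of 0.277. DESeq2 passed 64 genes (47 higher, 17 lower) and limma-voom with sample weights 390 (191 higher, 199 lower), with 1190 and 2650 at an unadjusted p under 0.05. On simulated data for this comparison DESeq2 made 19 false calls, beside 4 in edgeR and 4 in limma-voom. The simulated libraries shared 1 profile apart from depth and the changed genes, with none set apart like replicate 1. They therefore do not show how many of the 64 and 390 genes are false calls. With DESeq2's size factors in edgeR the 1077 genes at an unadjusted p under 0.05 were 533 higher and 544 lower. Within the libraries of the 20190809 prefix, which leaves out replicate 1 at 250 ng/bee, edgeR passed 248 genes, of which 212 rose and 36 fell, and the other prefix holds 1 library and gives no value. The rises were 1.06 at most with a median of 0.46, and the falls reached -0.85 with a median of -0.44. Nrk1 rose by 0.49 ± 0.10 (40.5 ± 4.74 CPM, n = 4, against 28.8 ± 2.86 CPM, n = 5, adjusted p = 0.0301 in edgeR) and NFRKB fell by 0.42 ± 0.10 (101 ± 7.71 CPM against 136 ± 8.62 CPM, adjusted p = 0.0434), the only 2 of the 248 with a symbol. In 233 of the 248 the 2 groups did not overlap, beside 971 of all 9560 genes and a chance share of 1.59%. The 248 were chosen on these same libraries, so their separation largely follows from that choice and adds no support. With all 15 libraries all 248 kept their direction, at a median size of 0.28 in place of 0.45, while with 1 surrogate variable 180 did, at 0.14, and with the length correction 243. These fits share 9 of the 10 libraries with the fit that chose the genes. Within this prefix, the count was 0 without control replicate 1 or 3, 69 without control replicate 2, 64 without control replicate 4 and 231 without control replicate 5. It was 0 without replicate 2, 4 or 5 at 250 ng/bee and 483 without replicate 3 at that dose.

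Fold changes at 250 ng/bee followed transcript length. The median log2 fold change was 0.17 over the 1281 genes with transcripts of 165 to 1108 nt and -0.15 over the 1280 genes of 4457 nt or more, and at 25 ng/bee it was 0.06 and -0.04. The slope of log2 CPM per doubling of length was 0.0364 ± 0.0231 in the control, 0.00555 ± 0.0452 at 25 ng/bee and -0.0419 ± 0.0124 at 250 ng/bee (SD, n = 5). Every library at 250 ng/bee lay below every control library, a difference of -0.0783 (two-sided exact permutation p = 0.00794, the smallest that 5 against 5 can give, adjusted p = 0.0238 over 3 comparisons). The slope test was not among the planned tests, and its adjustment covers only these 3 comparisons. Slopes at 25 ng/bee did not differ from the control by more than the spread (exact permutation p = 0.262), and 250 against 25 ng/bee gave -0.0475 (exact p = 0.0397, adjusted p = 0.0595). The 212 genes that rose without replicate 1 had a median length of 1303 nt and the 36 that fell 3259 nt. With the length correction, 0 genes passed edgeR with all 15 libraries, 645 at an unadjusted p under 0.05, and 59 passed without replicate 1.

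**Figure D3:**
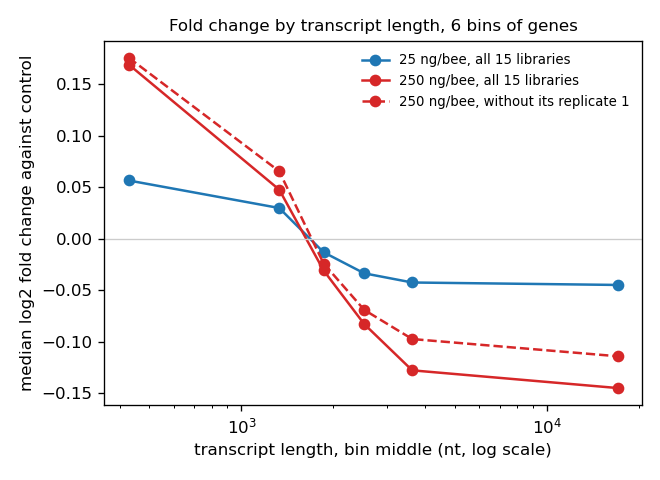
Median log2 fold change against the control (vertical axis) over 6 bins of genes by transcript length (nt, logarithmic horizontal axis) at 25 ng/bee and 250 ng/bee with all 15 libraries (solid lines) and at 250 ng/bee without its replicate 1 (dashed line). At 250 ng/bee the median went from 0.17 in the shortest bin to -0.15 in the longest, and at 25 ng/bee from 0.06 to -0.04.

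**Figure D4:**
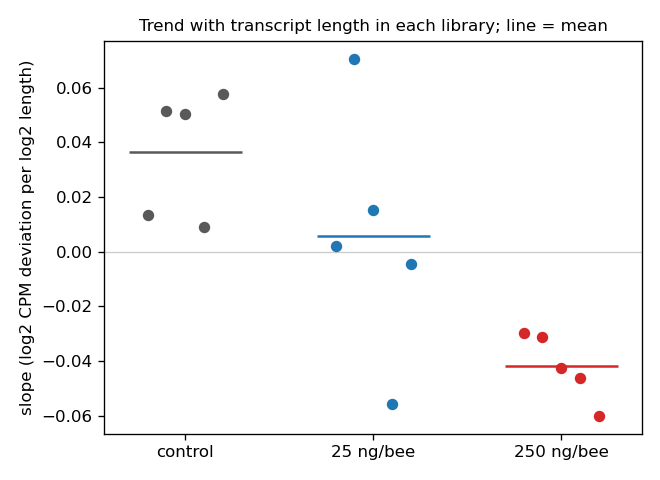
Slope of log2 CPM deviation per doubling of transcript length (vertical axis) in each library of the control, 25 ng/bee and 250 ng/bee groups, replicates 1 to 5 from left to right, with lines at group means. Control libraries lay between 0.00907 and 0.0576 and libraries at 250 ng/bee between -0.0599 and -0.0296.

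The doses were also compared with each other. Of 21 lists, camera passed 1, the ribosomal protein genes, 7 of 7 higher at 250 than at 25 ng/bee with a median of 0.43 (camera adjusted p = 6.56e-05, 3 of 5 libraries, and adjusted p = 0.805 with an estimated correlation), and without replicate 1 at 250 ng/bee the list did not pass (0.208). Among single genes, Lop2 (1.32 ± 0.40), JHBP-1 (1.06 ± 0.33), Adk1, an adenylate kinase (0.36 ± 0.12), Pburs (0.68 ± 0.23) and Rpl41 (0.47 ± 0.19) were higher at 250 ng/bee. Glurb (-0.36 ± 0.11), the histamine-gated channel gene Hiscl1 (-0.55 ± 0.17), CSP1 (-0.67 ± 0.25), Fstl5 (-0.31) and NFRKB (-0.27) were lower. None passed over all genes (adjusted p = 0.934 in edgeR). All 5 libraries at 250 ng/bee lay on the same side of the 25 ng/bee mean for each of these genes except Rpl41 (4 of 5) and Lop2 (3 of 5). The edgeR test passed 0 genes, with 477 at an unadjusted p under 0.05, and DESeq2 and limma-voom with sample weights passed 0, with 560 and 847. Over any of the 3 groups edgeR passed 0 genes, with 645 at an unadjusted p under 0.05.

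Fold changes of the 2 doses against the same controls correlated across the 9560 genes (r = 0.545, 71.3% with the same sign), where genes are not independent replicates. Unchanged groups simulated against these controls gave r = 0.504 (0.467 to 0.539 in 20 data sets) and 66.7% with the same sign. The covariance was 0.0421 beside 0.0352 in the simulation (0.0311 to 0.0374), a difference of 0.00686. With the controls split between the doses, r was 0.0556 on average (-0.0588 to 0.147). Limma passed 0 of 14930 transcripts at either dose, with 557 at an unadjusted p under 0.05 at 25 ng/bee and 695 at 250 ng/bee, beside 746.5 that chance gives on average, and transcripts were not tested with another tool. The 695 became 1457 without replicate 1 at 250 ng/bee and 1014 with quantile normalization, with 0 transcripts passing in either.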

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

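The tests of the length trend on the genes that passed without replicate 1 at 250 ng/bee, and of that library's depth or prefix as the source of the trend, were chosen only after the result was seen, as was the length correction itself. In 24 of 273 groups of 5 libraries, over the totals, marker lists and genes examined, 1 library lay far from the other 4 by Dixon's test. Chance picks about 1 in 20 groups of independent, normally distributed values. Gene values were CPM without a logarithm and came from the same libraries, so this rate is only a rough guide.

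Replicate 1 at 250 ng/bee held 29208991 counts and the others 6834898 to 11180170. The same library held 168100 CPM of Mrjp1 (others 22000 to 59960) and 3.01 CPM of Gstcd (0 in the others). Control replicate 4 held 3538 CPM of Apid1 (50.3 to 299 in the others), 4832 CPM of LOC406142 (46.3 to 1109), 4386 CPM of LOC406144 (207 to 1266) and 6.24 CPM of Gstcd (0 to 1.29). Replicate 3 at 25 ng/bee was also high in immune genes, with 430 CPM of Apid1 (35.8 to 101), 1680 CPM of LOC406142 (98.0 to 543) and 44.0 CPM of PGRP-S3 (17.2 to 22.0), and low in fat body genes, with a mean log2(CPM + 1) of 5.23 (6.28 to 6.58).

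Control replicate 5 was high in muscle and neuronal genes, with 199 CPM of TpnCI (52.0 to 84.4 in the others), 207 CPM of TpnCIIIa (9.08 to 33.5), 350 CPM of the sodium channel gene Para (256 to 278), 573 CPM of Syx1A (430 to 468) and 60.9 CPM of mGlutR1 (42.2 to 45.0). Control replicate 2 held 710 CPM of the chaperone gene Hsc70-3 (294 to 384) and 60.8 CPM of nAChRa8 (66.2 to 67.5), and control replicate 3 held 27.8 CPM of Lop2 (16.8 to 18.4). Replicate 1 at 25 ng/bee held 8446 CPM of the opsin gene Lop1 (3502 to 4486). At 250 ng/bee, replicate 4 held 411 CPM of TpnCI (71.3 to 163) and 0.857 CPM of Burs (1.20 to 1.31). Replicate 3 held 611 CPM of LOC406144 (180 to 299) and a mean log2(CPM + 1) of 4.06 over odorant-binding and chemosensory genes (4.50 to 4.66).

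Nrk1, NFRKB and 246 genes without a symbol passed edgeR at 250 ng/bee without replicate 1, and 0 passed with it (1144 at an unadjusted p under 0.05). Of 100 splits of the 9 libraries, only the real split, 1 in 100, gave as many (highest other 2). A random split of these 9 libraries is thus an unlikely source of the count. The splits do not cover the choice of this fit among others that gave 0, so chance is not excluded. Thinning replicate 1 to 9774054 counts left 0 genes in each of 5 draws, which argues against its depth, and with the length correction 54 calls stayed (median size 0.51 before, 0.53 after) while 194 ended at a smaller size and kept 78.7% of it (0.44, quartiles 0.39 to 0.53, before and 0.35, quartiles 0.28 to 0.44, after, with 186 still at an unadjusted p under 0.05), which argues against length as the whole source. A batch of replicate 1 is a candidate explanation: over the 248 genes ranked first without it, its median change in their direction was -0.563 with 20.6% of genes on the same side, beside 0.175 to 0.408 and 82.3% to 98.0% in the 4 other libraries held out in turn. Each held-out library was scored against the same controls that ranked the genes, which favours positive values. Since genes passed only without replicate 1, its low value partly restates that result. A pool of bees that responded otherwise stays open and untested, and cannot be told apart from a batch, since the other prefix holds this library alone.

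Short transcripts were higher and long ones lower at 250 ng/bee, a difference of -0.0783 in slope. After adjustment for the share of the 20 most abundant genes, 98.5% of it was kept (exact permutation p = 0.00794), and each of the 4 libraries other than replicate 1 lay at least 0.0402 below every control library, so neither a few abundant genes nor that library's depth or prefix accounts for it. Length-dependent RNA quality or library preparation was tested within genes, over 1173 isoforms of 313 genes, where the slope difference was 0.0308 (95% interval -0.134 to 0.195, exact permutation p = 0.619), an interval that holds both 0 and the value across genes and is widened by replicate 1 (-0.239, beside 0.0407 to 0.0862 in the other 4). Without that library, a setting chosen after the values were seen, the difference was 0.0911 (95% interval -0.0112 to 0.194, exact permutation p = 0.0635), against such a loss in the other 4, so the answer depends on 1 library and a technical loss of long transcripts and a response of the bees to the dose cannot be told apart here. A dose effect on long genes stays open and untested.

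The ribosome and respiratory chain lists were higher and the receptor and synaptic lists lower at 250 ng/bee in camera with its preset correlation (adjusted p = 0.657 to 0.708 with an estimated correlation), and 19 of 100 splits of the libraries passed 5 or more lists (highest other 7, real 5), so chance can not be excluded. The length trend may account for part of the higher values of the short lists: with its correction the larger adjusted camera p of ribosome and oxidative phosphorylation genes was 0.590, with medians going from 0.36 and 0.19 to 0.12 and 0.02, and their medians stood at the percentiles 91.8 and 66.6 of length-matched lists. The ribosome median also rested on replicate 1, going from 0.36 to 0.05 without it (adjusted p = 0.769) while the slope difference stayed (-0.0814) and the median of its length-matched lists went from 0.27 to 0.15, so how much of it is length and how much that library stays open. For receptors and synaptic genes the larger adjusted camera p was 0.110 after correction, with medians going from -0.27 and -0.29 to -0.16 and -0.15. Both stood low among length-matched lists (percentiles 0.44 and 1.40). The random lists were matched in mean expression as well as length, so their medians do not reflect length alone. They were drawn gene by gene without correlation between genes, so such percentiles can overstate how rare a median is. Gland, immune, odorant-binding and cuticle lists, which did not pass camera with all 15 libraries uncorrected, stood at 0, 0, 0.02 and 0.47. The trend and a separate fall of receptor and synaptic genes therefore cannot be told apart. Muscle and P450 genes stood at the percentiles 100 and 0.02.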

How the results depend on the processing

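Tests with the length correction, the marker scores, fry's mixed p, list tests within 1 prefix and combinations with the prefix were chosen only after the result was seen. Counts of genes stayed at 0 under every setting run at 25 ng/bee and between the doses (edgeR, DESeq2 and limma-voom, with 77 to 588 genes at an unadjusted p under 0.05 at 25 ng/bee). Over the 3 groups they stayed at 0 under every setting run, all of them in edgeR. At 250 ng/bee the count was 64 in DESeq2, 390 in limma-voom with sample weights, 248 with the 20190809 prefix only, 59 with that prefix and the length correction, and 0 to 248 with 1 library left out, where replicate 1 at 250 ng/bee gave 248, its replicate 3 gave 2 and the others 0. The 2 are LOC413083 (log2 fold change 3.05) and LOC112935903 (2.80), named after their values were seen. Of the 248, limma-voom called 143 and DESeq2 30, and for the other differences the cause was not tested.

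Lists at 25 ng/bee passed in 1 case without the low-count filter and 1 with the length correction, the P450 list each time (adjusted p = 0.0499 and 0.0424), and in 0 to 4 cases with 1 library left out. At 250 ng/bee the 5 lists became 0 with an estimated correlation, 0 in fry's directional and 0 in fry's mixed test, 2 with the 20190809 prefix only (receptors and P450), and 2 to 6 with 1 library left out, 2 without replicate 1 and 3 without replicate 3 at 250 ng/bee. Within the prefix, receptors and P450 each had an adjusted p = 0.722 in camera with an estimated correlation. Most random splits of the control and 250 ng/bee libraries of this prefix passed 2 or more lists at the preset correlation, as many as the real split. The P450 list also passed with DESeq2's size factors (0.0400) and without the low-count filter (0.0315). For each of these the cause was not tested. Transcripts passed in 0 to 1 cases at each dose, 1 of LOC727235 without replicate 2 and 1 of LOC409444 without replicate 5 at 25 ng/bee, and 1 of LOC411554 without replicate 3 at 250 ng/bee, chosen after their values were seen (the cause was not tested). The correlation of the doses went from 0.545 to 0.0556 with the controls split, where by construction shared control values no longer enter both, and was 0.581 without replicate 1.

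Whether replicate numbers pair the libraries is not stated in the labels and was not settled by the data. Of 15 pairs of the same number, 6 had a correlation over 0.1 (-0.0767 to 0.325, mean 0.0866). Of the 15, 8 correlated best with their own number out of 5 candidates. Random numbering would give fewer on average, which is a hint from the data and not from the design. Between the doses, replicates 3 to 5 had 0.325, 0.160 and 0.254. Replicates 1 and 2 had -0.0105 and 0.0254. With the replicate block, 2 lists passed at 25 ng/bee (P450 at 0.0134 and receptors at 0.0459), the P450 list passed at 250 ng/bee (0.00751), counts of genes with all 15 libraries stayed at 0, and with the 20190809 prefix 670 genes passed in place of 248. No other call changed with the block.

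For named genes, 19 values, all at 250 ng/bee, passed a threshold that they missed with all 15 libraries in edgeR, each in the same direction. No scaling moved the median gene by more than 0.1 on the log2 scale. At these depths and 5 pools per group, 38.8% of genes changed 1.5-fold at 250 ng/bee were recovered in simulated data, where depth was not varied on its own. The simulated genes were independent and no library was set apart, so recovery in the real libraries may be lower.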

Other observations

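The permutation tests of marker lists were added to the plan, and the splits were drawn as planned, but their count for lists between the doses was taken only after the result was seen. Gland products made up a large and variable part of the brain libraries. The 14 genes of the hypopharyngeal and salivary gland list held 14.4% ± 7.97 of the counts in the control, 14.2% ± 3.35 at 25 ng/bee and 12.4% ± 6.53 at 250 ng/bee (SD, n = 5), and their mean log2(CPM + 1) did not differ between the groups by more than the spread (exact permutation p = 0.802 for 25 ng/bee and 0.833 for 250 ng/bee against the control, two-sided). Mrjp1 had 76000 ± 58110 CPM in the control, 67440 ± 18390 at 25 ng/bee and 68570 ± 57480 at 250 ng/bee. Def1, the defensin gene, was the most abundant of the 12 tested immune genes, with a mean of 1.40% of all counts. Of the other marker lists, cuticle genes held 0.0435%, neuron genes 0.160%, muscle genes 0.233%, glia genes 0.255%, fat body genes 0.425%, retina genes 0.548% and odorant-binding and chemosensory genes 0.559% of the counts in the control, and none of the 24 marker comparisons passed (smallest exact permutation p = 0.143, muscle at 250 ng/bee, adjusted p = 0.952).

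Other splits of the libraries into groups of the same sizes were drawn 100 at a time. With a real count of 0, all 100 splits gave as many by definition, so they decide nothing about such counts. The highest other counts were 1 for genes at 25 ng/bee, 7 for genes at 250 ng/bee and 17 for genes between the doses. They were 20 for genes over any of the 3 groups, 10 for lists and 4 for transcripts at 25 ng/bee, and 365 for transcripts at 250 ng/bee. Most other splits at 25 ng/bee passed at least 1 list at camera's preset correlation. A pass of a list at that correlation alone therefore carries little weight. For lists between the doses, where the ribosome list was the 1 that passed, 84 of 100 splits passed 1 or more (highest other 10, real 1), so chance can not be excluded. The split with 365 transcripts passed 2 genes and 3 lists, and may point to a structure of the samples, which was not tested.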
